A study of Mus musculus with 18 samples.

How the data were processed

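RNA was measured on 18 Illumina mouse expression arrays, 3 at each of 6 stages from E11.5 to E16.5. Per the labels, ventricles of hearts from embryos with a green fluorescent protein (GFP) knock-in at Wt1 were dispersed with enzymes, GFP-positive cells were sorted by FACS and lysed straight after the sort, total RNA was isolated on RNeasy columns, and biotin-labelled cRNA was hybridized. The population carries the mark (M) in the labels, which do not say what the letter stands for. The deposited values were linear probe intensities that the authors had quantile-normalized between arrays: the sorted values of the 18 arrays differed by at most 0.0874%. GenomeStudio 2011.1 is named in the submitters' processing notes, without the settings of any step. The intensities ran from 83.8 to 17358 with a median of 104 and a mode of 99.0, and they bore no sign of background subtraction. A further table of values that were not normalized has 36 columns, 18 of intensity and 18 of detection p, under names that match no sample. It was not used here, so no detection p and no chip could be given to an array.

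Background was corrected with normexp (limma 3.58.1 in R 4.3.3, offset 16) and the values were put on log2, where they ran from 4.02 to 14.08. Because quantile normalization had been done, it was not repeated, and the number of probes above background, 20200 or 20201 on every array, says nothing about the depth of an array. The number of arrays, 3 per stage, limits the precision. The planned filter on detection p was replaced by a limit on the deposited intensity of 105.4, which is the mode of the values plus 1.64 SD of the spread below the mode (one-sided p of 0.05 in a normal background). Probes above it on at least 3 of the 18 arrays were kept, 25405 of 45281 (56.1%). The limit corresponds to 5.02 on the log2 scale. A gene named in the text that was not above the limit on any array of a stage has only a bound there. Its change is then given as at least N-fold, from the mean of the brighter stage against the lowest value of any probe above background on an array, averaged over the 3 arrays of the dim stage.

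Gene symbols came from the platform annotation given with the data. It pairs 34885 probes with 1 symbol and 18 with several and leaves 10378 without a name. Of the named probes 34807 were found by Entrez identifier in the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols changed. The tested probes stand for 12882 named genes. Wt1, Tnnt2 and Mki67 have no named probe and were not analysed here. In lists and named genes, a gene with several probes is represented by the probe with the highest mean over all arrays. Another probe of Tbx3, Tgfbr2, Bmp7, Junb, Nes, Pdgfra, Myh6, Xist and Eif2s3y had the opposite sign between E11.5 and E16.5 without passing the test. Adult globin genes and the Hspa1a and Hspa1b pair have near-identical copies, whose probes cannot be assigned to 1 copy.

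All 18 arrays entered 1 linear model with a coefficient per stage (limma lmFit and eBayes). The contrasts were E16.5 against E11.5, the 5 steps of 1 day, the linear and the quadratic trend over the 6 stage means, and a moderated F test over the stages. Each was adjusted by the Benjamini-Hochberg method over the 25405 probes, with a threshold of 0.05. Standard errors (SE) are those of the moderated test, and the spread of a stage is its SD over 3 arrays. Gene lists were tested with limma camera at a preset correlation of 0.01 and adjusted over the 30 lists tested, and again with a correlation estimated from the residuals and with fry. The contrasts, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls between E11.5 and E16.5 with an adjusted p under 0.05 and no overlap between the arrays of both stages, the 3 largest rises and falls of each step by the same conditions, the 5 largest and 5 smallest quadratic coefficients with an adjusted p under 0.05, and the 5 smallest p values of the F test. From each list it took up to 4 members that passed, by the size of the change, or the 2 largest changes where fewer than 2 passed. It also took Wt1, Tnnt2, Mki67, Tbx18, Tcf21, Aldh1a2, Myh6, Myh7, Pecam1, Pdgfra and Hbb-bh1 whatever their values. Predicted and clone names were left out.

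The 31 lists covered markers of epicardium and mesothelium, endothelium and endocardium, fibroblasts and mesenchyme, smooth muscle and pericytes, erythroid cells, macrophages and leukocytes, and neural crest and Schwann cells. They also covered the cardiomyocyte sarcomere, calcium handling and ion channels, cardiac transcription factors, the cell cycle, cell cycle inhibitors, fatty acid uptake and oxidation, oxidative phosphorylation, glycolysis, the retinoic acid, BMP, Wnt, Notch and FGF pathways, epithelial to mesenchymal transition, epithelial junctions, basement membrane and elastic fibre, complement, imprinted growth genes, interferon and MHC class I, cytosolic ribosomal proteins, the hypoxia response, the immediate early and dissociation response, genes named in the literature as WT1 targets, and sex-linked genes. They hold 524 distinct genes, of which 480 were named on the array.

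The replicate numbers in the labels were checked for pairing by the correlation of same-numbered arrays' deviations from their stage means. All 3 correlations were above 0.1 for 3 of the 15 pairs of stages. The only compared pair among them was E15.5 with E16.5 (0.283, 0.190 and 0.333), where the fit with the replicate number as a block is therefore given beside the result. For E11.5 with E16.5 the correlations were 0.0867, 0.145 and 0.0263. Over all pairs of stages the same-numbered array correlated best in 36 of 45 comparisons, with a median same-number correlation of 0.100. A weak pairing may thus run beyond E15.5 and E16.5, and the main model has no term for it. Counts with a replicate block over all stages are given among the alternatives.

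The alternatives were values without background correction (which are the authors' values on log2), no filter, a stricter intensity limit on all 18 arrays, an intensity trend with robust estimation, array weights, a replicate block, only the arrays of the stages compared, leaving out each array in turn, a minimum log2 change of 1, and for lists the estimated correlation, fry and the mean of a gene's probes. Median scaling without quantile normalization and a block for the chip were planned too and could not be run on these values. Added after the data had been seen were normexp with an offset of 50, centring on the probes above background on all arrays, leaving out E13.5 replicates 2 and 3 together, averaging the E14.5 arrays to 1 sample, and a replicate block within E15.5 and E16.5 alone. The tests were tried on simulated data for 25405 probes, of which 200 changed at the last stage only and a further 200 changed evenly day by day, 400 in all. For E16.5 against E11.5, 22 of 50 probes changed at the last stage by a log2 of 0.5 were recovered, and all 50 at 1, at 1.5 and at 2. For E15.5 against E16.5, 42% were recovered at 0.5, 98% at 1 and 100% above that. Of 360 probes called in the simulated E16.5 against E11.5 contrast, 338 were among the 400 changed ones of either kind and 22 (6.11%) had no change. Of 30 lists 0 were called where none was changed. The simulated probes varied independently of one another, without correlation between genes or between same-numbered arrays. The list result therefore says nothing about lists whose members vary together, such as the endothelial list with an estimated correlation of 0.465.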

Results

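The data follow 1 sorted population of the embryonic mouse heart over 6 successive days. Cells positive for GFP expressed from the Wt1 locus, which the series title calls cardiomyocytes, were taken from ventricles on every day between E11.5 and E16.5. Wt1 encodes a zinc finger transcription factor known from the epicardium. Each stage was measured on 3 arrays, 18 in all, and 25405 probes entered the tests. The purpose stated by the submitters is a profile of gene expression in these cells through the stages. Of 480 genes that were both on the fixed lists and named on the array, between 318 (E16.5) and 331 (E15.5) were detected on all 3 arrays of a stage, with 323 at E11.5, 326 at E12.5, 328 at E13.5 and 323 at E14.5. Nothing in the labels says that the replicates are separate litters or cultures, so the p-values measure only the spread between these samples.

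The stages followed one another along the first principal component, which held 38.5% of the variance. Its scores lay between -36.1 and -35.0 at E11.5, between -21.0 and -19.9 at E12.5, between -0.311 and -0.0777 at E14.5 and between 28.6 and 42.4 at E16.5, and the scores of E15.5 (20.1 to 33.1) overlapped those of E16.5. Arrays of 1 stage correlated with r between 0.980 and 0.994. On the second component E13.5 replicates 2 and 3 stood apart at -32.5 and -34.3, while E13.5 replicate 1 lay at -8.45 and had E14.5 replicate 1 as its closest array (r = 0.990). E12.5 replicate 1 was likewise closer to E13.5 replicate 1 (r = 0.986) than to the other arrays of its own stage (mean r = 0.984), which bears on the counts between these stages, and no array was moved or left out. Each E16.5 array had the same-numbered E15.5 array as its closest, with r of 0.990, 0.993 and 0.988 for replicates 1, 2 and 3. Their mean r with the other E16.5 arrays was 0.985, 0.987 and 0.983. E15.5 replicates 1 and 2 were also closest to the same-numbered E16.5 arrays. The E14.5 arrays were the closest to one another, with r of 0.992 to 0.994. Eif2s3y, a Y-linked gene, was at 4.46 ± 0.15 (SD, n = 3) at E14.5, not above background, and Xist, the RNA of the inactive X chromosome, at 10.45 ± 0.19 (n = 3). Both were above background on 11 arrays, Eif2s3y without Xist on 4, and Xist without Eif2s3y on 3, which were the E14.5 arrays.

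**Figure D1:**
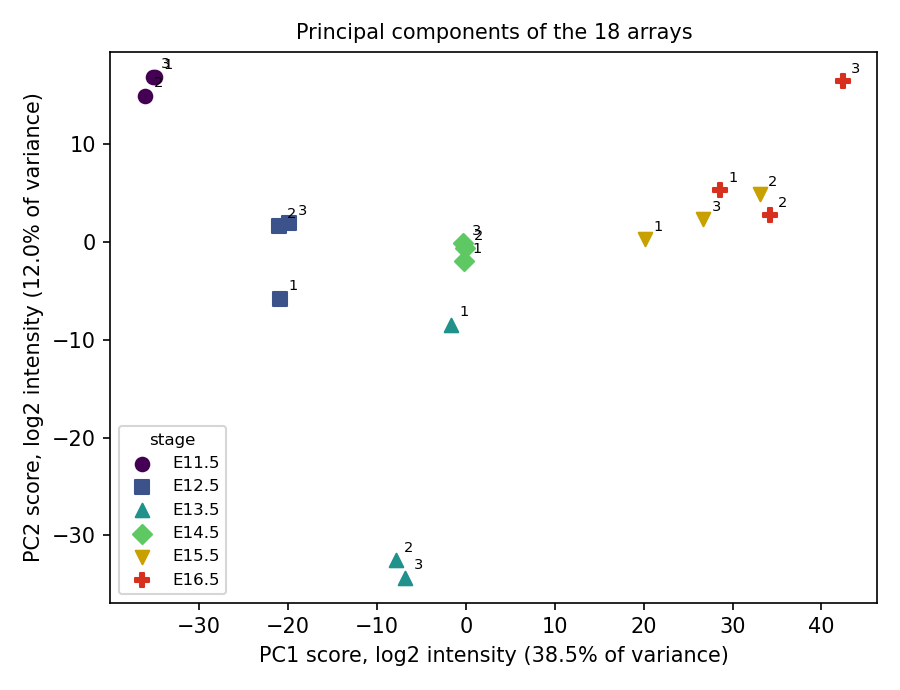
Scores of the 18 arrays on the first principal components of the log2 intensities of the tested probes, the first with 38.5% of the variance. Each point is 1 array, coloured by stage and marked with its replicate number, and the stages run from left to right with E13.5 replicates 2 and 3 lowest, at -32.5 and -34.3.

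From E11.5 to E16.5, genes of the muscle cell were among those with the largest rises and the largest falls. Ckm, the muscle creatine kinase, rose 82.0-fold (log2 change 6.36, SE 0.16, adjusted p = 2.58e-19), from 5.62 ± 0.33 to 11.98 ± 0.13 (mean log2 intensity ± SD, n = 3 arrays per stage). Myom2, which encodes the M-band protein myomesin 2, was not above background at E11.5 and rose by at least 4.17 on the log2 scale (SE 0.18). Casq2, the calcium-binding protein of the cardiac sarcoplasmic reticulum, rose 16.6-fold (SE 0.16 on the log2 scale), and Perm1, a regulator of muscle mitochondria, rose 14.7-fold (SE 0.16). Myl1, a myosin light chain, ended 13.4-fold lower (log2 change -3.74, SE 0.17), Mybphl, a relative of myosin-binding protein C, 14.9-fold lower (-3.89, SE 0.20) and Col2a1, a fibrillar collagen known from cartilage, 23.2-fold lower (-4.53, SE 0.21, with 1 of 3 arrays above background at E16.5).

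The other genes with the largest rises were the adult beta globin genes Hbb-bs (82.3-fold, SE 0.40 on the log2 scale) and Hbb-bt (81.5-fold, SE 0.42), the alpha globin gene Hba-a1 (34.9-fold), Dcn, the matrix proteoglycan decorin (23.2-fold), Cav1, the caveolar protein caveolin 1 (16.8-fold), Ptgds, a prostaglandin D synthase (14.4-fold), Cox8b, a cytochrome c oxidase subunit of muscle (14.3-fold), and the heat shock gene Hspa1a (log2 change 3.81). The other genes with the largest falls were the platelet chemokine gene Pf4 (log2 change -3.58), Lyz1, a lysozyme gene (10.8-fold lower), Dkk3 (7.55-fold lower), Igdcc3 (6.84-fold lower), Treml1 (6.20-fold lower), Emb (6.18-fold lower) and Arid3b (5.87-fold lower). Ppbp and Tubb1, which encode another platelet chemokine and a platelet tubulin, were not above background at E16.5 and were at least 5.99-fold and at least 5.72-fold lower. In all, 4915 of 25405 probes changed (19.3%), 2267 upwards, standing for 1573 genes, and 2648 downwards, standing for 1819 genes. By at least 2-fold, 552 rose and 315 fell.

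**Figure D2:**
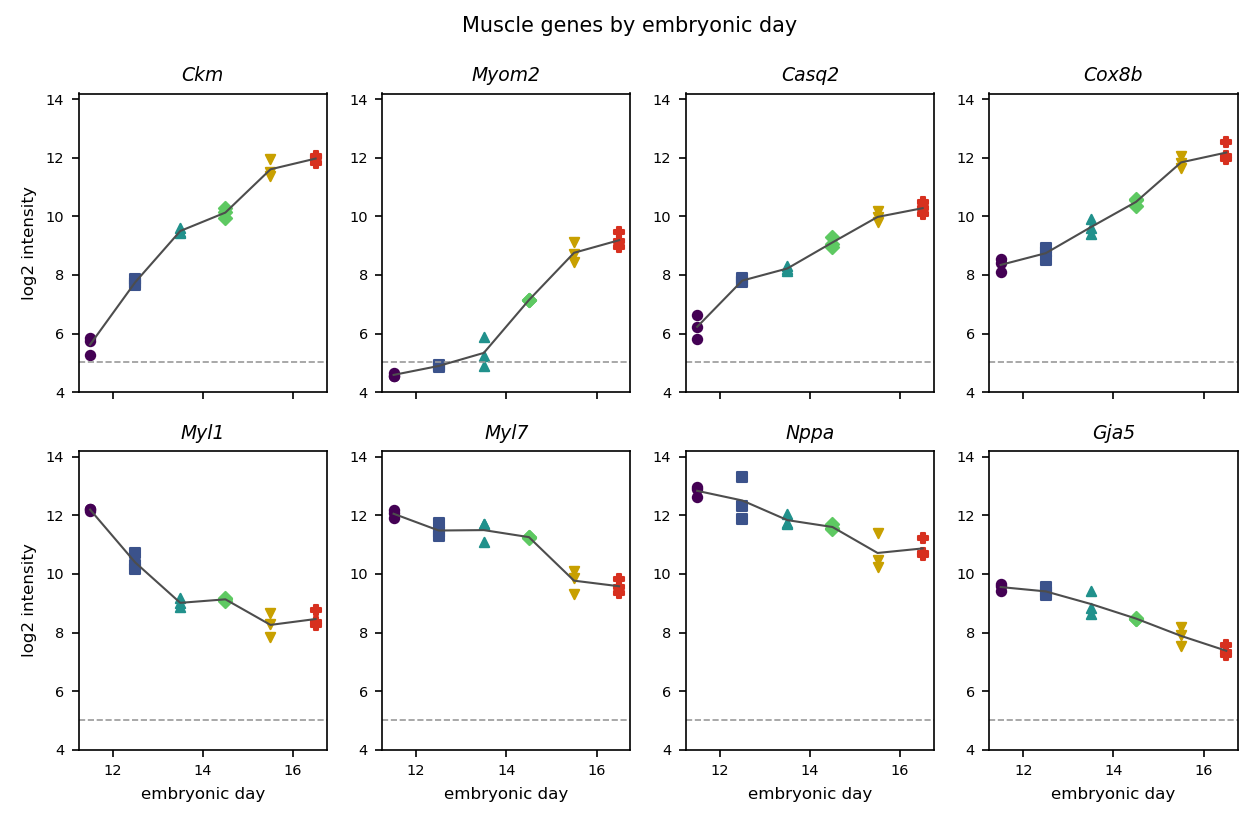
Log2 intensity of 8 muscle genes (vertical axis) against embryonic day (horizontal axis). Points are single arrays, 3 per stage, lines join the stage means, the dashed line marks the background limit of 5.02, and Ckm went from 5.62 to 11.98.

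Of the metabolic lists, those of fatty acid oxidation and oxidative phosphorylation rose, and those of glycolysis and the hypoxia response were not called. Over the same days the mean of the fibroblast markers rose by 1.80 on the log2 scale and that of the endothelial markers by 0.83. Of 19 measured genes of fatty acid uptake and oxidation, 16 rose, 0 fell and 3 did not pass the test. Examples are the acyl-CoA dehydrogenase genes Acadl (3.13-fold, SE 0.15 on the log2 scale, n = 3 per stage) and Acadvl (2.42-fold), the thiolase gene Acaa2 (2.78-fold) and the fatty acid binding protein gene Fabp3 (2.68-fold). Adjusted over the list alone, 17 passed, the list's median log2 change was 0.66, and its adjusted p in camera was 1.04e-10 (adjusted p = 0.000824 with an estimated correlation). Of 18 oxidative phosphorylation genes 9 rose, 0 fell and 9 did not pass, the rises including the oxidase subunit genes Cox8b, Cox7a1 (2.26-fold) and Cox6a2 (1.73-fold) and the complex I gene Ndufa9 (1.65-fold). This list's median was 0.41, 10 members passed adjusted over the list alone, and its adjusted p was 2.13e-06 (adjusted p = 0.00171 with an estimated correlation). Glycolysis genes went both ways. Of 17 members 3 rose, such as Eno3 (2.25-fold) and Aldoc (2.02-fold), and 5 fell, with Slc2a1, the glucose transporter GLUT1, 4.86-fold lower, a list median of -0.15, 8 passing adjusted over the list alone and an adjusted p of 0.793. Among 13 hypoxia response genes Egln3 (6.05-fold), Ndrg1 (4.50-fold) and Ddit4 (2.26-fold) rose, Slc2a1 fell, 9 did not pass, 4 passed adjusted over the list alone, and the adjusted p was 0.145.

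Genes of contraction and excitation split. Of 22 sarcomere genes 4 rose, including Cmya5 (3.39-fold, SE 0.13 on the log2 scale), the adult cardiac troponin I gene Tnni3 (2.07-fold) and Myoz2 (1.99-fold), and 2 fell, among them Myl7, the atrial regulatory light chain (log2 change -2.48, SE 0.18). The other 16 did not pass, 9 passed adjusted over the list alone, and the list's adjusted p was 0.0842 with a median of 0.15. Among the alternatives it was 0.0452 without background correction and 0.0481 with a normexp offset of 50. It was 0.138 with an estimated correlation and 0.145 without E16.5 replicate 1. Myh6 was at 11.99 ± 0.10 at E11.5 and changed by -0.19 (SE 0.16, adjusted p = 0.498). The change of Myh7 was 0.50 (SE 0.20, adjusted p = 0.0804). That p came to 0.00133 without E16.5 replicate 3, 0.00297 with array weights and 0.419 without E16.5 replicate 1. Of 17 calcium handling and ion channel genes 8 rose, such as Casq2 and the calcium-binding protein gene S100a1 (4.27-fold), and 2 fell, the gap junction gene Gja5 (log2 change -2.18, SE 0.17) and Nppa, the atrial natriuretic peptide gene (-1.97, SE 0.26). The list's median was 0.27, 11 members passed adjusted over the list alone, and the adjusted p was 0.0302 (adjusted p = 0.138 with an estimated correlation and 0.0862 with the mean of a gene's probes). Cardiac transcription factors gave 5 rises and 4 falls among 19. Tbx3 fell by 1.33 (SE 0.18), Irx4 ended 1.64-fold lower (SE 0.16), Hand1 was at least 1.52-fold lower and Nr2f2 at least 1.32-fold higher, 9 passed adjusted over the list alone, and the adjusted p was 0.504. Over the same days the mean of the fibroblast markers described next stood 1.80 higher on the log2 scale at E16.5 than at E11.5, and that of the endothelial markers 0.83 higher.

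Of the markers of other cell types, most fibroblast and endothelial ones rose, and the few macrophage markers detected at E11.5 fell. Of 19 fibroblast and mesenchymal markers 16 rose, such as Dcn, Ogn (12.6-fold, SE 0.26 on the log2 scale, n = 3 per stage), Lum (12.3-fold) and Col1a1 (11.3-fold), 1 fell and 2 did not pass. Pdgfra rose 2.83-fold (SE 0.25). The list's median was 1.77, 18 members passed adjusted over the list alone, and the adjusted p was 6.34e-16 (adjusted p = 0.0369 with an estimated correlation). Of 21 endothelial and endocardial markers 14 rose, among them the tight junction gene Cldn5 (10.7-fold), Esam (3.32-fold), Robo4 (2.97-fold) and Pecam1 (2.15-fold), and 2 fell, including Plvap (2.65-fold lower). The median was 0.93, 17 passed adjusted over the list alone, and the adjusted p was 2.55e-06 (adjusted p = 0.198 with an estimated correlation). The mean of this list stood at 0.39 ± 0.20 relative to E11.5 at E13.5, at -0.10 ± 0.02 at E14.5 and at 0.63 ± 0.34 at E15.5 (SD, n = 3 each). Of 8 macrophage and leukocyte markers 0 rose and 3 fell, Lyz2 at least 3.09-fold, Laptm5 2.23-fold and Coro1a 2.20-fold, with a median of -0.17 and 3 passing adjusted over the list alone. These 3 were the only members detected on all arrays of E11.5, so the list says little about the others. The adjusted p was 0.0302 (adjusted p = 0.138 with an estimated correlation, 0.0662 without background correction and 0.0501 with a normexp offset of 50).

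The 11 smooth muscle and pericyte markers gave 4 rises, among them Rgs5 (at least 5.58-fold), Kcnj8 (2.97-fold) and Pdgfrb (2.73-fold), and 1 fall, that of the actin-binding protein gene Tagln, at least 3.30-fold lower. The median was 0.06, 5 passed adjusted over the list alone, and the adjusted p was 0.0879. In the erythroid list, 3 of 8 members rose, including Hba-a1 and the heme synthesis gene Alas2 (at least 1.79-fold), and 4 fell, among them the embryonic globin gene Hbb-bh1 (at least 1.87-fold lower). Hbb-y, another embryonic globin gene, fell by 0.97 (SE 0.32, adjusted p = 0.0339), a call lost in 8 of 16 alternatives (highest adjusted p = 0.301, without E11.5 replicate 3). The erythroid list's median was -0.29 and the test pointed downwards, while its mean was 0.41, 7 members passed adjusted over the list alone, and the adjusted p was 0.923. Ngfr was the 1 tested gene of the neural crest and Schwann cell markers, which were therefore not tested as a list, and it rose 1.54-fold (SE 0.15, adjusted p = 0.00345).

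**Figure D3:**
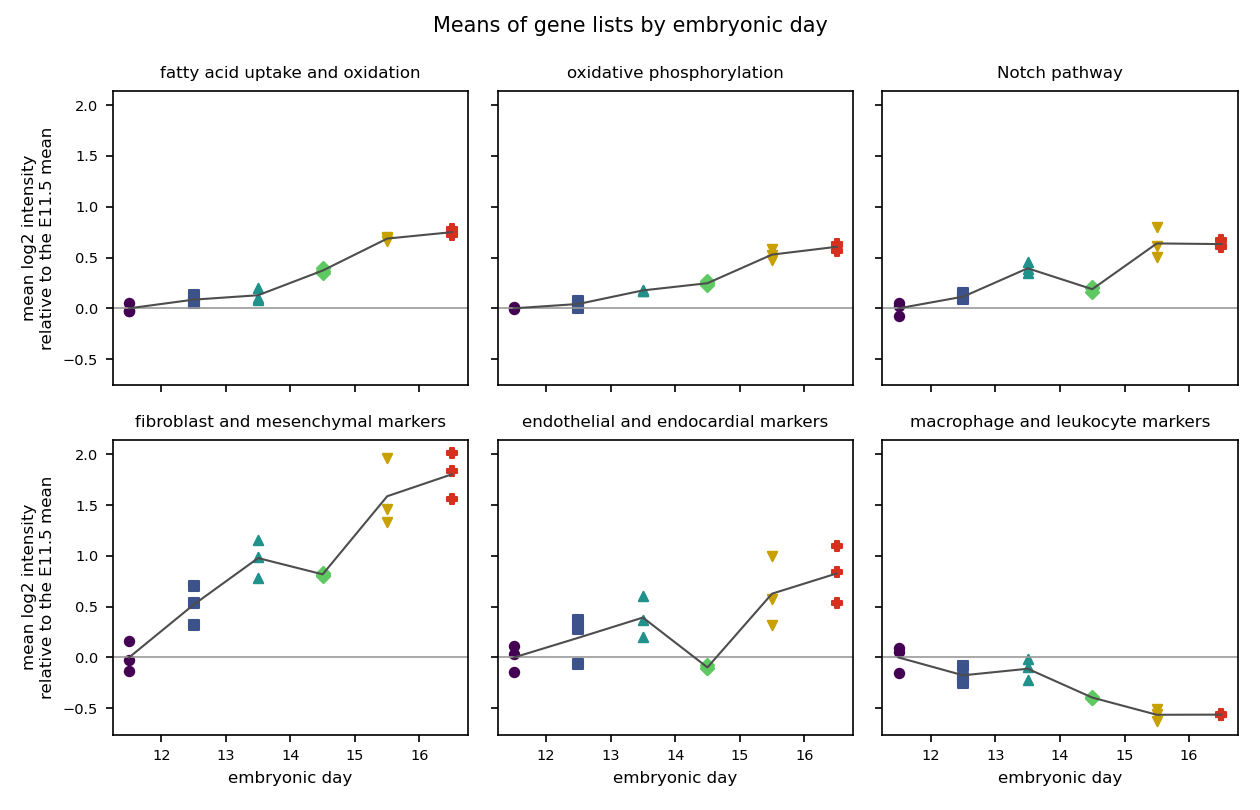
Mean log2 intensity of 6 gene lists relative to their mean at E11.5 (vertical axis) against embryonic day (horizontal axis). Points are single arrays, 3 per stage, and lines join the stage means. At E16.5 the fibroblast mean stood at 1.80, the endothelial mean at 0.83, the fatty acid mean at 0.75 and the macrophage mean at -0.56.

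Epicardial and mesothelial markers showed 3 rises and 7 falls among 15. Tcf21, a transcription factor gene of epicardium and cardiac fibroblasts, rose 4.42-fold (log2 change 2.14, SE 0.19, adjusted p = 7.56e-09), and the keratin genes Krt8 (log2 change -1.55, SE 0.14), Krt19 (-1.44, SE 0.15) and Krt18 (-1.18, SE 0.16) fell. Tbx18, an epicardial transcription factor gene, fell by 0.58 (SE 0.15, adjusted p = 0.00670, and 0.0555 without E16.5 replicate 2). Aldh1a2, the retinaldehyde dehydrogenase of the epicardium, was not above background at E11.5 and was at least 1.02-fold higher at E16.5 (adjusted p = 0.0398), a call lost in 10 of 16 alternatives (highest adjusted p = 0.198, without E16.5 replicate 3). The list's median was -0.26, 10 members passed adjusted over the list alone, and the adjusted p was 0.137. The epithelial junction list, which shares the 3 keratins, had 0 rises and 4 falls among 11, with a median of -0.06 and a mean of -0.41. Of these members 5 passed adjusted over the list alone, and the adjusted p was 0.0403. The call was lost in 8 of 14 alternatives other than fry (adjusted p = 0.138 with an estimated correlation, 0.0558 with a replicate block and 0.0729 with the mean of a gene's probes, among others).

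Of 18 genes of epithelial to mesenchymal transition 9 rose, such as the matrix metalloproteinase gene Mmp2 (5.68-fold, SE 0.22 on the log2 scale), the TGF-beta receptor gene Tgfbr2 (3.62-fold) and Snai2 (1.82-fold), and 2 fell. The median was 0.45, 13 passed adjusted over the list alone, and the adjusted p was 0.0126 (adjusted p = 0.200 with an estimated correlation). In the retinoic acid pathway 1 of 9 genes passed, Aldh1a2, the change of Rarb was 0.33 (SE 0.15, adjusted p = 0.123), 0 passed adjusted over the list alone, and the adjusted p was 0.472. The 14 genes named in the literature as WT1 targets gave 3 rises, such as Snai1 (1.41-fold), and 3 falls, such as Bmp4 (2.06-fold lower), with a median of 0.01, 7 passing adjusted over the list alone and an adjusted p of 0.820. Basement membrane and elastic fibre genes gave 7 rises among 17, including Col6a1 (9.44-fold, SE 0.20), Col6a2 (4.78-fold) and Nid1 (4.76-fold), and 2 falls. The median was 0.38, the mean 0.67, 13 passed adjusted over the list alone, and the adjusted p was 0.00256 (adjusted p = 0.144 with an estimated correlation). The fibroblast markers rose over the same days, with a mean 1.80 higher at E16.5. Of 6 complement genes 2 rose, Serping1 (3.88-fold) and Cfi (1.40-fold, which came to an adjusted p of 0.108 without E16.5 replicate 3), 2 passed adjusted over the list alone, and the adjusted p was 0.201.

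Signalling pathways moved in different directions. Of 14 Notch pathway genes 8 rose and 0 fell, among them the target gene Nrarp (8.03-fold, SE 0.16 on the log2 scale), the receptor genes Notch4 (2.16-fold) and Notch1 (1.90-fold) and Heyl (at least 1.72-fold). The median was 0.47, 8 passed adjusted over the list alone, and the adjusted p was 0.000224 (adjusted p = 0.0261 with an estimated correlation). Beside this list and the other pathways here, the endothelial markers stood 0.83 and the fibroblast markers 1.80 higher in the mean at E16.5. Of 19 Wnt pathway genes 3 rose and 9 fell, such as Dkk3, Wnt5a (4.63-fold lower, SE 0.16), Rspo3 (2.03-fold lower) and Sfrp1 (2.02-fold lower). The median was -0.33, 12 passed adjusted over the list alone, and the adjusted p was 0.0292 (adjusted p = 0.138 with an estimated correlation and 0.0631 without background correction). Of 15 BMP pathway genes 2 rose, including Id1 (2.22-fold), and 7 fell, including Id2 (3.27-fold lower), Bmp7 (2.20-fold lower) and Bmp10 (at least 1.68-fold lower). The median was -0.17, 9 passed adjusted over the list alone, and the adjusted p was 0.0879. FGF pathway genes gave 1 rise, Fgf18 (at least 1.64-fold), and 3 falls, among them Fgf10 (1.91-fold lower) and Fgf7 (at least 1.49-fold lower), among 12. Adjusted over the list alone 7 passed, and the adjusted p was 0.301.

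Growth and cell cycle genes changed in part. Beside them, the fibroblast markers stood 1.80 and the endothelial markers 0.83 higher in the mean at E16.5 than at E11.5. Of 12 cell cycle inhibitors 6 rose, such as Cdkn2c (3.68-fold, SE 0.13 on the log2 scale) and Btg1 (1.89-fold), while Cdkn1c, which encodes p57, fell by 2.33 (SE 0.17) from 13.77 ± 0.09 at E11.5 (n = 3). The median was 0.38, 8 passed adjusted over the list alone, and the adjusted p was 0.0172 (adjusted p = 0.0732 with an estimated correlation). Of 25 cell cycle genes 1 rose, Top2a (1.52-fold, adjusted p = 0.0154, lost in 3 of 17 alternatives with a highest value of 0.0864 without E11.5 replicate 1), and 5 fell, among them the replication licensing genes Mcm2 (1.53-fold lower) and Mcm5 (1.42-fold lower) and Ccne1 (1.54-fold lower). The median was -0.05, 6 passed adjusted over the list alone, and the adjusted p was 0.485. Among 13 imprinted growth genes Dlk1 rose 13.1-fold (SE 0.23), and 6 fell, including Cdkn1c, Mest (2.61-fold lower) and Ndn (1.87-fold lower). The median was -0.33, 8 passed adjusted over the list alone, and the adjusted p was 0.0332 (adjusted p = 0.200 with an estimated correlation and 0.0973 without E16.5 replicate 3).

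Of 13 immediate early and dissociation response genes 7 rose and 0 fell, such as Hspa1a, Ier3 (4.66-fold, SE 0.22 on the log2 scale) and Junb (3.04-fold). The median was 0.76, 11 passed adjusted over the list alone, and the adjusted p was 0.000140 (adjusted p = 0.138 with an estimated correlation). By E16.5 the fibroblast markers stood 1.80 and the endothelial markers 0.83 higher in the mean beside this list and the next. Of 9 interferon and MHC class I genes 3 rose, Ifitm3 (4.89-fold, SE 0.18), H2-D1 (log2 change 0.58) and B2m (1.38-fold), with a median of 0.23 and 3 passing adjusted over the list alone. The call of H2-D1 was lost in 4 of 17 alternatives (highest adjusted p = 0.135, without E16.5 replicate 2) and that of B2m in 3 of 17 (0.109, without E16.5 replicate 3). The adjusted p was 0.0332 (adjusted p = 0.138 with an estimated correlation and 0.0705 without E11.5 replicate 3). Of 10 cytosolic ribosomal protein genes 0 rose and 3 fell, led by Rpl4 (1.67-fold lower, SE 0.13), with a median of -0.21 and 3 passing adjusted over the list alone. The adjusted p was 0.0711 (0.0339 without background correction and 0.198 with an estimated correlation). None of the 4 sex-linked genes passed, and the list's adjusted p was 0.820. In total 15 of 30 lists were called, 11 upwards and 4 downwards, of which 4 were called with an estimated correlation.

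At the first step, from E11.5 to E12.5, Hspa1a rose 14.1-fold (log2 change 3.82, SE 0.42, adjusted p = 2.82e-06), from 5.10 ± 0.20 to 8.92 ± 0.35 (SD, n = 3). The adult globin genes Hbb-bs and Hbb-bt rose 10.3-fold (SE 0.40 on the log2 scale) and 9.85-fold (SE 0.42). Pf4 fell by 3.41 (SE 0.17, adjusted p = 6.87e-12), from 8.82 ± 0.38 to 5.41 ± 0.23, Tubb1 ended 4.29-fold lower, and Ppbp was at least 5.99-fold lower. Relative to E11.5 the list means at E12.5 were 0.79 for the erythroid and 0.79 for the immediate early and dissociation response genes, 0.52 for the fibroblast and 0.19 for the endothelial markers. In all 207 probes rose and 198 fell, 405 together, and 210 were called without E11.5 replicate 2 and 224 without E12.5 replicate 3.

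From E12.5 to E13.5, Dlk1, the gene of a Notch-related transmembrane protein, rose 3.38-fold (log2 change 1.76, SE 0.23, adjusted p = 0.000157), Ckm 3.37-fold (1.75, SE 0.16) and Hbb-bt 3.57-fold (1.83, SE 0.42, adjusted p = 0.0215, lost in 6 of 17 alternatives with a highest value of 0.131 without E13.5 replicate 3). The neuropeptide gene Gal fell by 1.46 (SE 0.16, adjusted p = 1.69e-05), Hspa1a ended 4.41-fold lower (SE 0.42 on the log2 scale) and the mitochondrial gene ND5 2.80-fold lower (SE 0.28). Relative to E11.5 the fibroblast mean stood at 0.52 at E12.5 and 0.98 at E13.5, the endothelial mean at 0.19 and 0.39. Here 241 probes rose and 292 fell, 533 together. This count rested on single arrays, with 1850 called without E13.5 replicate 1, 153 without E13.5 replicate 2, 143 without E13.5 replicate 3, 182 without E12.5 replicate 2 and 216 without E12.5 replicate 3. The calls of Hspa1a and ND5 were each lost in 3 alternatives, Hspa1a with an adjusted p of 0.0732 under the robust variance trend and ND5 with 0.0538 without E13.5 replicate 3, and the change of ND5 was -0.60 with E13.5 replicate 1 alone.

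From E13.5 to E14.5, Myom2 rose 3.50-fold (log2 change 1.81, SE 0.18, adjusted p = 1.81e-05), from 5.34 ± 0.50 to 7.14 ± 0.01 (SD, n = 3), the beta globin gene Hbb-b2 3.66-fold (1.87, SE 0.44, adjusted p = 0.0196, lost in 10 of 16 alternatives, with 0.110 under the robust variance trend and a change of 0.90 without background correction) and the spectrin gene Sptb 2.52-fold (1.33, SE 0.19). Eif2s3y was at least 5.19-fold lower (adjusted p = 0.000158), the actin-bundling gene Fscn1 fell by 1.10 (SE 0.19), and Gstp1, a glutathione transferase gene, fell by 1.19 (SE 0.24, lost in 6 of 17 alternatives, with an adjusted p of 0.0921 without E13.5 replicate 3). The mean of the fibroblast markers was 0.98 at E13.5 and 0.82 at E14.5, that of the endothelial markers 0.39 and -0.10. In all 360 probes rose and 439 fell, 799 together. The count was 2444 without E13.5 replicate 1 and between 109 and 244 without any 1 of the other arrays of these stages. With E13.5 replicate 1 alone, the spread coming from the other stages, the count was 4, and the calls of Sptb (1.02, SE 0.23, adjusted p = 0.227), Fscn1 (-0.96, SE 0.27, 0.368) and Gstp1 (-0.48, SE 0.29, 0.907) were lost. With the E14.5 arrays averaged to 1 sample the count was 1, and with the changes as before and larger errors the calls of Eif2s3y (SE 0.52, adjusted p = 0.152), Sptb (SE 0.28, 0.478) and Fscn1 (SE 0.29, 0.478) were lost.

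From E14.5 to E15.5, Cldn5 rose 5.06-fold (log2 change 2.34, SE 0.37, adjusted p = 0.000415), Cav1 4.67-fold (2.22, SE 0.26) and Eif2s3y at least 8.19-fold. The embryonic globin gene Hbb-y fell by 3.30 (SE 0.32, adjusted p = 1.00e-06), from 9.05 ± 0.08 to 5.74 ± 0.53 (SD, n = 3), Col2a1 ended 5.18-fold lower (SE 0.21) and Lyz1 4.68-fold lower (SE 0.22). The fibroblast mean stood at 0.82 at E14.5 and 1.59 at E15.5, the endothelial mean at -0.10 and 0.63. In all 466 probes rose and 332 fell, 798 together. The count was 458, 452 and 411 without E14.5 replicates 1, 2 and 3 in turn, and 327 without E15.5 replicate 2. With the E14.5 arrays averaged to 1 sample, the spread coming from the other stages, it was 69, and Cldn5, its change still 2.34 with an SE of 0.56, was not called (adjusted p = 0.0896).

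From E15.5 to E16.5, 1 of 25405 probes changed in limma, and 936 had an unadjusted p under 0.05. It stands for Mkks, a chaperonin-like gene chosen here because the count was small, which rose by 1.73 (SE 0.22, adjusted p = 0.00135), from 4.86 ± 0.22 to 6.59 ± 0.51 (SD, n = 3), with 1 of 3 arrays above background at E15.5. Between these stages the fibroblast mean went from 1.59 to 1.80 and the endothelial mean from 0.63 to 0.83. With the replicate number as a block within these stages 3 probes passed, those of Mkks, of Rbp7, a retinol-binding protein gene (1.35, SE 0.19, adjusted p = 0.00653), and of Cavin4, a muscle caveolar gene (0.94, SE 0.15, adjusted p = 0.0356). Without background correction, under the stricter limit or with a normexp offset of 50, 0 probes passed, and 8 passed without E15.5 replicate 2, 3 without E15.5 replicate 1 and 2 without E16.5 replicate 1.

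Over all 6 stages 5895 probes (23.2%) differed by the F test, standing for 4105 genes. The smallest p values belonged to Ckm, Myom2, Perm1, Cox8b and the small heat shock protein gene Hspb6, which rose 11.3-fold from E11.5 to E16.5 (log2 change 3.50, SE 0.12, n = 3 per stage). A linear trend over the days was found for 6364 probes, 2923 rising and 3441 falling, with Ckm rising by 1.26 per day on the log2 scale. By camera 13 lists had a linear trend, 10 upwards and 3 downwards, of which 3 were called with an estimated correlation, and all 13 were among the 15 called between E11.5 and E16.5. The lists of epithelial junctions (adjusted p = 0.0672) and of interferon and MHC class I genes (adjusted p = 0.0704) were called only between E11.5 and E16.5. The fibroblast list had an adjusted p of 1.90e-13 for the trend (adjusted p = 0.0620 with an estimated correlation).

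A curved course was found for 1029 probes. Of these 582 were higher at the middle days than a line through the stages would give, led by Hbb-y, which stood at 6.02 ± 0.93 at E11.5, 9.22 ± 0.41 at E13.5 and 5.04 ± 0.30 at E16.5 (SD, n = 3). The globin genes Hbb-bt, Hbb-bs and Hba-a1 followed, and Chn2, which encodes a Rac GTPase-activating protein, went from 5.45 ± 0.24 to 7.63 ± 0.28 at E13.5 and to 5.96 ± 0.07. The other 447 were lower at the middle days than such a line, led by Pf4, Eif2s3y, Ppbp, Alox12, the platelet lipoxygenase gene, and Myl1. Such a course need not be lowest at the middle days. The mean of Myl1 was 12.20 at E11.5, 9.01 at E13.5 and 8.46 at E16.5. Eif2s3y was not above background on any E14.5 array, where Xist was. Leaving out each array in turn, the count of curved courses ran from 710 without E11.5 replicate 2 to 1737 without E13.5 replicate 1. Another grouping of the 18 arrays gave 959.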

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

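Between E11.5 and E16.5 rises made up 46.1% of the changed probes, and 45.2% without background correction, 45.3% with a normexp offset of 50 and 46.8% after centring. Of 149 counts under settings other than leaving out 1 array 122 stayed within 1.5-fold, of 1739 values of named genes 1702 kept their call, and of 270 values of lists 236 did. The cause of a shift was not tested unless stated.

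With array weights the counts were 728 from E11.5 to E12.5, 1305 to E13.5, 2542 to E14.5 and 1659 to E15.5, and 1775 for curved courses. With only the arrays of the compared stages 119 probes differed between E12.5 and E13.5. A log2 change of at least 1 left 552 rises and 315 falls between E11.5 and E16.5, and 97, 52, 38 and 168 probes at the first 4 steps, which follows from the added condition. From E15.5 to E16.5 the count was 0 without background correction, 0 under the stricter limit on all arrays and 0 with an offset of 50. Without E13.5 replicates 2 and 3 the counts were 47 from E12.5 to E13.5, 4 from E13.5 to E14.5 and 465 for curved courses. With the E14.5 arrays averaged to 1 sample they were 289, 1 and 69 for the steps from E12.5 to E15.5 and 368 for curved courses. Both settings, like the offset of 50, were chosen after seeing the data, and both leave 1 value at a stage with the spread taken from the other stages, which by itself lowers the counts. Averaging left the changes themselves as they were (Cldn5 2.34 from E14.5 to E15.5, Sptb 1.33 and Fscn1 -1.10 from E13.5 to E14.5). With E13.5 replicate 1 alone some changes shrank, ND5 from E12.5 to -0.60 from -1.48 and Gstp1 to E14.5 to -0.48 from -1.19, and others did not, Hspa1a from E12.5 being at -2.53 and Hbb-b2 to E14.5 at 2.05.

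With the replicate number as a block within E15.5 and E16.5, added because same-numbered arrays of these stages correlated, 3 probes differed. A replicate block over all stages kept every count within 1.5-fold: 6575 by the F test, 2441 rises and 2906 falls between E11.5 and E16.5, 482, 759, 1196, 942 and 1 at the steps, 3123 and 3726 linear trends and 1247 curved courses. Of 30 lists, 4 were called between E11.5 and E16.5 and 3 for the trend with an estimated correlation, against 24 and 25 by fry.

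Leaving out each array in turn gave 4903 to 6986 probes by the F test, 1819 to 2197 rises and 1927 to 2520 falls between E11.5 and E16.5. The steps ranged from 210 to 397, 143 to 1850, 109 to 2444, 327 to 908 and 1 to 8, and trends from 2541 to 3025 rising and 2911 to 3603 falling, with 710 to 1737 curved courses. For lists only the 6 arrays of E11.5 and E16.5 were left out in turn, giving 13 to 15 between these stages and 11 to 15 for the trend. The range for the trend therefore does not cover leaving out an array of a stage between them. The highest counts at the steps into and out of E13.5 came without E13.5 replicate 1 and the lowest without replicate 3. At the first step, leaving out E11.5 replicate 2 or E12.5 replicate 3 moved the count more than 1.5-fold (210 and 224), as did leaving out E12.5 replicates 2 and 3 or any E13.5 array at the next, any array of both stages from E13.5 to E14.5, any E14.5 array or E15.5 replicate 2 from E14.5 to E15.5, and E15.5 replicates 1 and 2 or E16.5 replicate 1 at the last.

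The sex-linked genes depended on single arrays and reversed. The change of Xist between E11.5 and E16.5 was -0.68, and ran from -1.62 without E16.5 replicate 2 to 1.14 without E16.5 replicate 1. That of Eif2s3y was -0.31, and ran from -0.65 without E16.5 replicate 1 to 0.16 without E16.5 replicate 2. None of these passed a test.

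Median scaling without quantile normalization and a block for the chip were not run. Intensities that were not background-subtracted compress changes near the background, so the size of a change in dim probes depends on the correction.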

Other observations

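Several genes known from platelets fell between E11.5 and E12.5. Pf4 stood at 8.82 ± 0.38 at E11.5 and 5.41 ± 0.23 at E12.5 (log2 intensity ± SD, n = 3), 10.6-fold lower (SE 0.17 on the log2 scale, adjusted p = 6.87e-12). Tubb1 ended 4.29-fold lower, Treml1 4.25-fold lower (SE 0.15, adjusted p = 3.99e-09), Alox12 4.04-fold lower and Ppbp at least 5.99-fold lower. Chosen after their values were seen, the platelet receptor genes Gp9 (1.94-fold lower), Gp1bb (at least 1.78-fold lower), Itga2b (1.43-fold lower, adjusted p = 0.0252) and F2rl2 (at least 1.66-fold lower) were lower too, from levels of 5.55 to 6.09 at E11.5 that lay not far above the background limit of 5.02. No list of platelet genes was fixed beforehand and none was tested as a group.

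The tests on other groupings of the arrays were chosen before the data were examined. Among 100 groupings of the 18 arrays into 6 sets of 3, the real one included, 1 gave as many probes as the real one by the F test (5895, highest other 104), 1 for the linear trend (6364, highest other 21), 1 for curved courses (1029, highest other 959) and 3 for lists with a linear trend (13, highest other 14). The curved courses and the lists were thus nearly matched or matched by other groupings.

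For each pair of stages only 10 splits into 3 and 3 exist, too few for a share under 0.05. The real split was the 1 with the most probes of 10 for E11.5 against E16.5 (4915, highest other 0), for E11.5 against E12.5 (405, highest other 0), E12.5 against E13.5 (533, highest other 155), E13.5 against E14.5 (799, highest other 0) and E14.5 against E15.5 (798, highest other 0), and for lists between E11.5 and E16.5 (15, highest other 9). The 155 came from the split that exchanges replicate 1 of E12.5 with replicate 1 of E13.5. For E15.5 against E16.5, 4 of 10 splits gave as many as the real 1, and the highest gave 79, grouping both replicate 1 arrays with E15.5 replicate 3 against both replicate 2 arrays with E16.5 replicate 3, which points to a structure of these samples other than the stage. Among the 4 splits that part all 3 same-numbered pairs the highest other count was 1, and the 6 that do not reached 79.

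On the rise and turnover of globin genes, the tests were chosen only after the result was seen. Adult globin genes rose from E11.5 to E16.5 and Hbb-y fell from E14.5 to E15.5, and RNA of red blood cells carried into the sorted samples is a candidate explanation. Within stages, adult globin genes went with Alas2 and Slc4a1 over the 18 arrays (r = 0.897, permutation p = 0.00255, and rho = 0.917, permutation p = 0.00193, with 46656 permutations). Both were 0.00510 when adjusted together over the permutation p values of r and rho for the 2 relations computed. Without the 2 arrays farthest out r was 0.866 and rho 0.885. Alas2 was above background on 0 arrays of E11.5 and E12.5, and over the 9 arrays of E14.5 to E16.5, all with both markers above it, r was 0.985 (permutation p = 0.0139, 0.0185 adjusted, 216 permutations) and rho 0.950 (permutation p = 0.0278, 0.0278 adjusted), with 0.924 and 0.893 without the 2 arrays farthest out. Signal shared between probes of similar globin genes is argued against as the whole signal of Hbb-y. From E14.5 to E15.5 Hbb-y changed by -3.30 (SE 0.32), while the lowest change of 3 adult genes, that of Hba-a1, was 0.37 (adjusted p = 0.716). The fitted change of Hba-x was -1.24 (SE 0.20, adjusted p = 0.000488, also the median with Hbb-bh1), apart from that of Hba-a1 by -1.61 (SE 0.37). Hba-x was above background on 3 arrays of E14.5 and 0 of E15.5, so the size of its fall is not known. As no adult gene fell, its direction argues against shared signal as its whole signal too. For Hbb-bh1 this step decides nothing (-0.28, adjusted p = 0.396, 0 arrays above background at E15.5). From E11.5 to E16.5, however, the arrays of Hbb-bh1 went from 5.64 to 6.06 down to 4.54 to 4.98. Those of Hba-a1 went from 5.77 to 6.62 up to 10.65 to 12.32. Though Hbb-bh1 was dim, this argues against shared signal as its whole signal. A shared part stays open for all of them. The level of Hba-a1 reached 11.81 ± 0.21 at E15.5, none of the erythroid markers is in another list, and transcription in the sorted cells themselves, which a stricter GFP sort would separate from carried RNA, was not tested.

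On the rise of fibroblast and endothelial markers, the tests were chosen only after the result was seen. A falling share of 1 main cell type would raise the markers of every other type alike. From E11.5 to E14.5, among members detected on all arrays of E11.5, the medians of 14 fibroblast and 17 endothelial markers were 0.88 and -0.10. They were apart by 0.98 (permutation p = 0.000170). E14.5 was the only stage at which the endothelial mean was not above E11.5. From E12.5 to E16.5 that mean stood at 0.19, 0.39, -0.10, 0.63 and 0.83, and the fibroblast mean was above E11.5 throughout. The stage was chosen after the result was seen, and the 3 E14.5 arrays may share a source. The comparison therefore does not decide on this cause. A change in the types that rose stays open too. To E16.5 the fibroblast list exceeded the macrophage list by 1.94 (permutation p = 0.0111) with only 3 of 8 macrophage markers detected at E11.5, and those 3, Laptm5, Lyz2 and Coro1a, fell, the detected medians being apart by 2.79 (permutation p = 0.0610), which leaves this comparison open. A share of fibroblasts that differs between the sorted samples could be part of it, as the members went together within stages (mean residual correlation 0.346, highest of 10000 random lists 0.236), and so could a share of endothelial cells (0.465, highest of 10000 random lists 0.135). The permutation p values of the marker lists come from exchanging genes between lists as if the genes were independent. Since members went together, these p values may be too small, and they do not measure the spread between arrays. As a hypothesis only, fibroblast and endothelial cells are candidate sources, with Dcn 23.2-fold, Col1a1 11.3-fold and Cldn5 10.7-fold higher at E16.5, 2 fibroblast members (Fn1 and Vim) in other lists and 0 endothelial ones, and the ventricle expresses these genes too. A change in the Wt1-positive cells with day stays open, and a GFP sort with a second marker against these types would remove the candidate.

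On the close agreement of the E14.5 arrays, the tests were chosen only after the result was seen. Of 29 lists 15 had their lowest SD at E14.5 and at most 4 at any other stage, but this repeats that the arrays were the closest over all probes and decides nothing about 1 source of RNA or 1 pool behind the 3 arrays. The Y-linked genes differed at E14.5. Kdm5d, like Eif2s3y, was not above background on any of the 3 arrays, while Uty was above it on all 3 (5.83, 5.27 and 5.35). A shared sex of the embryos, to which Xist at 10.45 and Eif2s3y at 4.46 might point, was examined on 20124 probes outside the sex chromosomes. Of these 27.4% had their lowest SD at E14.5, against 19.5% at E11.5, the next highest. The closeness was thus not confined to sex-linked probes. Most of the 25405 tested probes lie outside the sex chromosomes, so this too repeats the closeness over all probes and does not decide its source. The labels name no pool, so whether the arrays share a source stays open.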
